A study of Rattus norvegicus with 5 samples.

How the data were processed

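The series profiled parotid glands, the salivary glands beside the ear, of 5 male Sprague-Dawley rats on Illumina bead arrays. Total RNA was amplified to biotin-labelled cRNA, per the labels' protocols. The labels describe an intraperitoneal injection of saline (the control group, n = 2 rats) or of isoproterenol, an agonist of beta-adrenergic receptors. Glands of isoproterenol rats were taken at 10, 30 and 60 min, with 1 rat at each time. The labels give the dose as 20 mg per g body weight. Such a dose would be extraordinarily large, so its unit is in doubt and the dose actually given is uncertain. The time between saline injection and death of the controls, the time of day and the array slides were not given in the sources used here. Each sample was hybridised to 1 array, so the 2 control arrays stand for 2 rats and each time stands for a single rat.

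The authors deposited a probe table with an intensity on a linear scale and a detection p-value for each of 22517 probes on each array. A detection p-value of an Illumina array is the share of negative control beads at least as bright as the probe. The deposited intensity table is named as non-normalized, but the sorted values of its 5 columns differed by a median of 0.029%, so the values had already been brought to the same quantiles. No background had been subtracted, since the smallest intensity was 43.1 and the lower quartile 64.6. A second deposited table holds the authors' processed values on a log2-like scale, with a median of 6.0015 on each array and the same rank order as the intensity on all 5 arrays. These log2 values are compressed at low intensity and were not centred per gene, and the transform that the authors used was not given in the sources used here. The software behind both tables was likewise not given in the sources used here.

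Precision is limited by the number of arrays. Between 9095 probes at 10 min and 9459 probes in control 2 had a detection p-value under 0.01, which is 40.4% to 42.0% of the probes.

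Gene names came from the platform annotation supplied with the series. It gave 13787 probes 1 gene symbol, which named 13336 genes, and left 8730 probes without one. No probe had several symbols. Of the Entrez identifiers, 13747 matched the rat reference table (assembly GRCr8), and 0 symbols needed an update beyond those in it. The array's genome build was not named, so no coordinates are given. For genes with several probes, lists used the probe with the highest mean log2 value.

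The intensities were background-corrected by normexp with parameters inferred from the detection p-values, given an offset of 16, quantile normalized and put on the log2 scale (neqc of limma 3.58.1 in R 4.3.3). A probe was tested when its detection p-value was under 0.01 on at least 1 array. This kept 10793 probes, of which 7769 had a gene symbol (7627 genes), and left out 11724. The offset and the background near the dim end shrink fold changes of dim probes.

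A linear model with 1 mean per group was fitted with lmFit and eBayes to all 5 arrays, and each time was compared with the control mean. The residual has 1 degree of freedom, from the pair of controls, and eBayes added 3.88 prior degrees of freedom around a prior SD of 0.186. Each lone isoproterenol rat was therefore assumed to vary as the control rats did. The same fit gave the difference between 60 and 10 min and a moderated F-test over the 3 times. A model with 2 groups compared all 3 isoproterenol rats with the controls, with 3 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested probes at 0.05. Beside the tests, a rule of size counted probes at least 1 from the control mean on the log2 scale and outside the range of the controls. The count of probes whose controls differ by at least 1 is the background for it. A difference between 2 single arrays has a larger sampling variance than that of 1 array from a mean of 2, so this background is not like for like.

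A total of 24 gene lists, covering processes and cell types, were fixed before the data were examined, as were the designs, the naming rule and most alternatives. They hold 509 listed names, of which 427 matched a gene of the annotation. For each list the median log2 difference was set beside its percentile among 10000 random lists matched on mean expression in 20 bins. This percentile describes these arrays and is not a test across rats. Members past the threshold were counted over all tested probes and adjusted over the list alone. Genes in several lists count in each.

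The text names, per time and direction, the 10 probes with the largest log2 difference among those past the limma threshold, with a gene symbol that is not a placeholder. Where fewer than 10 passed, the list was filled by size with probes at least 1 from the control mean, above background on the bright side and farther from both controls than these lie from each other. Up to 4 members of each gene list with the largest change at any time are named, and Adrb1, Fos, Nr4a1, Crem and amylase where measured. A further gene of this rule is not reported here. Other names were chosen after their values were seen, and the text says so. A probe with a detection p-value of 0.01 or more on every array of a group has only a bound there. Its fold is given as at least the ratio of the bright group's mean to the dim group's mean, with each dim array taken at the higher of the probe's own value and the lowest value among detected probes. Where neither group is above background no bound can be given, and list medians at bounds take such members as unchanged.

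Overlaps between times were set beside the overlap of independent lists and beside 100 simulated sets of unchanged arrays against the same controls, drawn with the moderated variances. Since moderation lowers the spread that the shared control mean brings, a further 100 sets were drawn with each probe's own variance between the controls, a choice made after the values were seen. Also chosen then was a repeat with a different control for each time, which shares no array and takes every probe at least 1 from its control. The tests were checked on simulated data with 10793 probes, in 5 runs per setting. Variances were drawn from the prior estimated on these arrays, with independent probes and treated arrays as variable as the controls. The check therefore shares the assumptions of the fit and cannot show how the tests behave where these fail. With 200 probes changed, the comparison of 60 min with control recovered 4.78% of changes of 1 on the log2 scale, 80.9% of changes of 2 and 98.5% of changes of 3, with a mean of 16.2 false calls. With 2400 probes changed it recovered 56.9%, 97.1% and 99.6%, with a mean of 82.6 false calls.

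Alternatives were no background correction, an offset of 50, median scaling, the authors' processed values, no filter on dim probes, a filter asking for detection on 2 arrays, an intensity trend in the prior variance, the mean of a gene's probes, a linear trend over time, and leaving out arrays. Alternatives chosen after seeing the data were a robust prior variance, the time trend as a result of its own, the level of skeletal muscle markers as a covariate, and leaving out probes whose controls differ by at least 1. Figures were drawn with matplotlib 3.10.9.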

Results

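Transcript levels were measured in parotid glands of 2 saline-injected control rats and of 3 rats killed 10, 30 or 60 min after isoproterenol, with 1 rat per time. Isoproterenol acts on beta-adrenergic receptors, which in parotid acinar cells drive amylase secretion through cAMP. Of 22517 probes, 10793 were above background on at least 1 array and were tested. The time course asks which genes change within the first hour. Between 9095 and 9459 probes were above background on each array. Since each time has 1 rat, differences from control have no replicate check on the treated side, and the limma tests take their spread from the 2 controls and a prior over all probes.

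In the 1 rat taken at 60 min, immediate early genes and cAMP and CREB target genes stood far above the controls. The time from saline injection to death of the controls was not given. An effect of isoproterenol therefore cannot be told apart from handling or a difference between rats. Crem, a cAMP-responsive transcription factor gene, rose by 5.10 ± 0.85 (SE) on the log2 scale, or 34.3-fold, from a control mean of 6.51 ± 1.49 (SD, n = 2). Its second probe rose by 4.36. Gadd45b, a growth arrest and stress gene, rose by 4.92 ± 0.51 (SE), or 30.3-fold. Slc7a5, a subunit of a large neutral amino acid transporter, rose 17.8-fold. The AP-1 gene Junb rose 17.6-fold, Nabp1, which encodes a single-stranded DNA binding protein, 17.5-fold, the MAP kinase phosphatase gene Dusp1 17.2-fold and the orphan nuclear receptor gene Nr4a2 16.8-fold. Rd3l rose 14.9-fold and the phosphatase gene Ptp4a1 14.6-fold. Adjusted p of these rises lay between 0.0281 and 0.0287 with limma. In all, 2634 of 10793 probes (24.4%) passed the limma threshold at 60 min, 1403 higher and 1231 lower, and 4538 had an unadjusted p under 0.05. Without the filter on dim probes, none of 22517 probes passed, although 5628 had an unadjusted p under 0.05. With a robust prior variance the calls of Crem's brighter probe and of Dusp1 were lost.

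**Figure D1:**
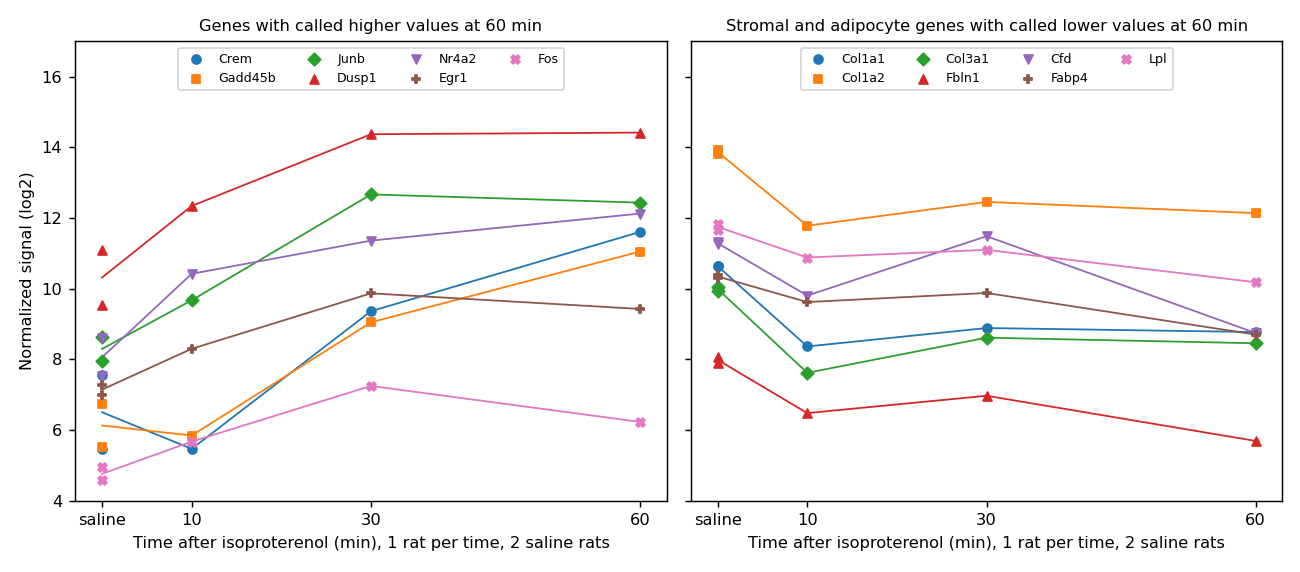
Normalized log2 signal of 7 genes called higher at 60 min (left) and 7 stromal or adipocyte genes (right) against time after isoproterenol in min. Each symbol is 1 rat, both saline rats are drawn at the left, and lines start from their mean. Dusp1 reached 14.42 at 60 min against 9.53 and 11.10 in the controls, and Col1a1 stood at 8.37 at 10 min against 10.63 and 10.65.

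Immediate early genes, the class transcribed first after a stimulus, were higher as a group. Of 31 measured members, 19 rose and 2 fell at 60 min (21 and 2 adjusted over the list alone), and their median was 1.11 higher, above all of 10000 matched random lists. The median was 0.66 with the authors' values and 0.73 without background correction. The zinc finger gene Egr1 rose 4.87-fold and Gadd45g, a relative of Gadd45b, 6.46-fold. Fos, the AP-1 gene of the same class, rose at least 2.26-fold (adjusted p = 0.0287 with limma), a bound because it was not above background in either control. Klf10 (-1.23) and Phlda1 (-2.24) fell; these members were singled out after their values were seen. Nr4a1 differed by 0.34 (adjusted p = 0.444). Nr4a3 stood 4.42 above the control mean but did not pass (adjusted p = 0.0732), since it was 3.42 higher in control 2 than in control 1. The list as a whole was 0.14 higher in control 2 than in control 1, at the 99.2 percentile of random lists.

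Genes transcribed in response to cAMP and CREB had a median 1.28 above control at 60 min (1.16 with members not above background at their bound), above all random lists. Of 20 measured members, 10 rose and 1 fell (11 and 1 adjusted over the list alone). Besides Crem, Nr4a2 and Junb, they included the repressor gene Nfil3, which rose by 3.46, a call lost with a robust prior variance. The member that fell was Pck1, a gluconeogenic enzyme gene named after its value was seen, which was at least 1.92-fold lower and not above background at 60 min. This list too was 0.30 higher in control 2 than in control 1, above all random lists. Without filtering out dim probes its 60 min median was 0.34.

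Feedback regulators of MAP kinase signalling had a median of 1.13, with 6 of 12 measured members higher and none lower by the test (7 and 1 adjusted over the list alone). By sign alone, 7 were higher and 5 lower. Dusp1, Dusp5 (8.48-fold), Dusp8 (5.82-fold by the brighter of its probes) and the EGF receptor inhibitor gene Errfi1 (6.41-fold) rose. The Dusp5 call was lost with a robust prior variance. The list was 0.30 higher in control 2 than in control 1, at the 99.9 percentile, and its 60 min median was 0.01 without filtering out dim probes. Among 7 measured EGF receptor ligands and growth factors, 3 rose and none fell (4 and 0 adjusted over the list alone). These were the stress cytokine gene Gdf15 (5.54-fold), the EGF receptor gene Egfr (at least 2.13-fold) and the ligand gene Tgfa (2.95-fold), while Vegfa was 0.80 higher without passing (adjusted p = 0.0546), although it passed with an offset of 50, without background correction and with the authors' values. The median of this list was 0.80, 0.53 with the authors' values and -0.12 without filtering out dim probes.

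Of 17 measured acinar secretory genes, which encode saliva proteins and parts of the secretory machinery, 1 rose at 60 min and none fell, with the same counts adjusted over the list alone. The median difference was 0.06, against 0.07 between the controls, but 8 of the 17 had control means above 14 on a scale that ended at 15.32. A rise of such genes is hard to see, so the median does not show that the list was stable. Oprpn, a secretory protein gene, rose 3.14-fold. Lpo, the lactoperoxidase gene, was 0.55 higher, and Bpifa2f (-0.55) and Scgb1c1 (-0.68) were lower, none past the threshold. Amylase (Amy1) differed by -0.02 ± 0.20 (SE), a sign that turned with median scaling, at a level of 15.05 near the top of the scale. Spt1, encoding salivary protein 1, lay outside this list and fell by 4.74 ± 0.88 (SE), or 26.7-fold (adjusted p = 0.0297). Its controls stood at 9.12 and 11.30, and its call was lost with a robust prior variance.

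Adipocyte markers were lower as a group at 60 min, and the strongest single decreases included genes outside that list. Car3, a carbonic anhydrase gene on the list of skeletal muscle markers, fell 9.88-fold, the stearoyl-CoA desaturase gene Scd 6.22-fold, the adipsin gene Cfd, on the adipocyte list, 5.82-fold, and G0s2, which encodes an inhibitor of triglyceride lipase, 5.48-fold. Ces1d, a carboxylesterase gene, fell at least 5.98-fold and was not above background at 60 min. Car3 did not rank the rats as most muscle markers did. It stood at 11.42 and 11.24 in the controls and at 10.32, 11.52 and 8.03 at 10, 30 and 60 min. Of 14 measured adipocyte markers, 8 fell and none rose (11 and 0 adjusted over the list alone), including Fabp4 (3.13-fold), Lpl (2.96-fold) and Cd36 (2.89-fold). The median of the list was -0.92, or -0.57 with members not above background at their bound, -0.48 with the authors' values and -0.05 between the controls. The F-box gene Fbxl20 fell 7.60-fold, the clock repressor gene Nr1d1 7.06-fold, the DNA repair gene Rad52 5.75-fold and Mss51 5.30-fold.

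Markers of connective tissue and vessels were lower at all 3 times. Of 15 measured endothelial and fibroblast markers, 13 fell at 60 min and none rose (15 and 0 adjusted over the list alone), with a median of -1.54. Fbln1, an extracellular matrix gene, fell 4.91-fold, and the collagen genes Col1a1, Col1a2 and Col3a1 fell 3.65-fold, 3.32-fold and 2.90-fold. The medians at 10 and 30 min were -1.37 and -0.86. No member passed over all tested probes at either time, and 11 were lower at each when adjusted over the list alone. The controls differed by a median of -0.10 in this list.

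**Figure D2:**
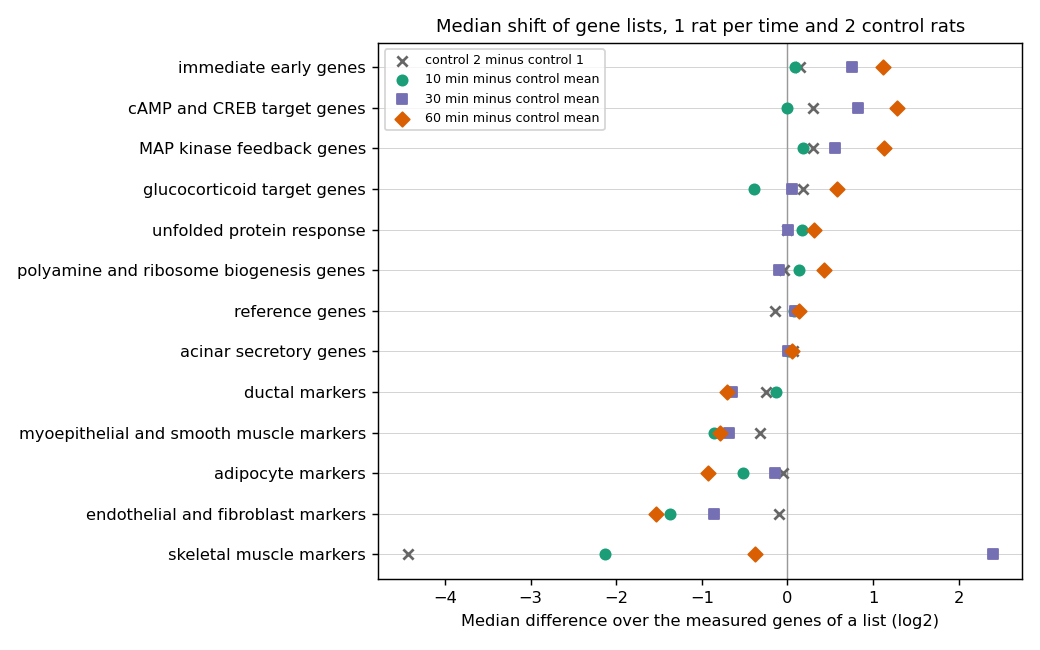
Median log2 difference over the measured genes of 13 gene lists (rows), with 1 symbol for each time against the control mean and crosses for control 2 minus control 1. At 60 min immediate early genes stood at 1.11 and endothelial and fibroblast markers at -1.54. Skeletal muscle markers differed most between the controls, by -4.44.

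Other cell type markers also differed between arrays. Skeletal muscle markers were 4.44 lower in control 2 than in control 1 in the median of 16 measured genes, and they lay 2.14 below the control mean at 10 min, 2.40 above it at 30 min and 0.38 below it at 60 min. None of them other than Car3 passed at any time, and the creatine kinase gene Ckm stood at 13.26 and 7.39 in the controls. The skeletal actin gene Acta1 differed by -5.69 in control 2 minus control 1, and the myosin light chain gene Myl11 stood at 12.85 and 6.84. Without control 1 the medians of the skeletal muscle list at 10, 30 and 60 min were -0.04, 4.81 and 1.80. Without control 2 they were -4.41, 0.05 and -2.98. Of 11 ductal markers, 3 fell at 60 min (6 adjusted over the list alone), Krt19 by 1.32, Krt7 by 1.14 and Scnn1b, a subunit of the epithelial sodium channel, by 1.13, with a median of -0.71 (-0.28 without filtering out dim probes). Atp6v1b1, of the same list, was 0.46 lower (adjusted p = 0.163). Of 8 myoepithelial and smooth muscle markers, 2 fell (3 adjusted over the list alone), Smtn 2.82-fold and Tagln 1.79-fold, with a median of -0.78 (-0.48 without control 1). The Smtn call was lost with the authors' values. Desmin (Des), also expressed in skeletal muscle, and Actg2 did not pass. Of 7 myeloid and mast cell markers, 2 fell (3 adjusted over the list alone), Fcer1g by 1.18 and Aif1 by 1.15, while Mrc1 and Tyrobp did not pass.

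**Figure D3:**
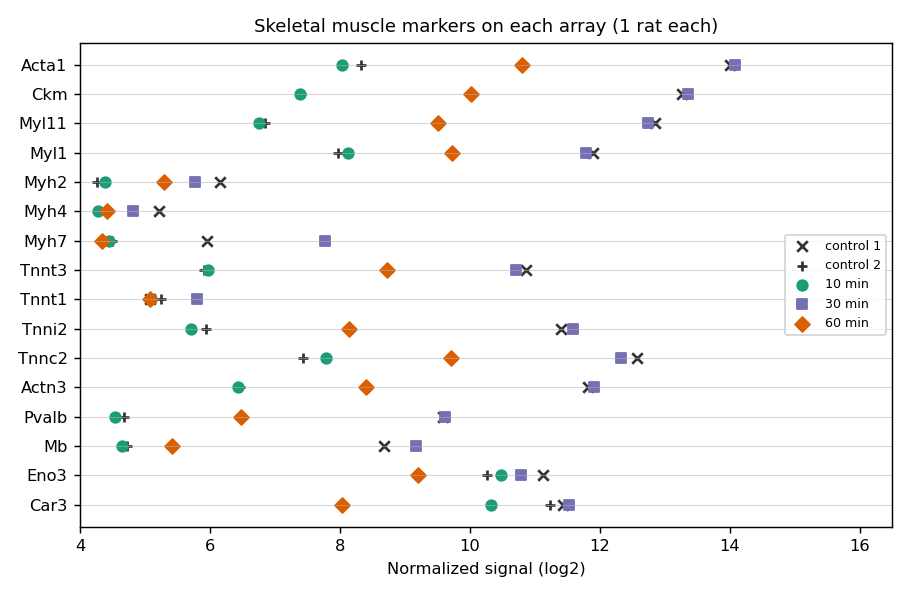
Normalized log2 signal of the 16 measured skeletal muscle markers (rows), with 1 symbol for each rat. For Ckm, control 1 (13.26) and the 30 min rat (13.36) lie far above control 2 and the 10 min rat, with the 60 min rat between them at 10.02.

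Among 10 lymphoid markers the chemokine receptor gene Ccr7 rose 3.74-fold (1 and 0 adjusted over the list alone), while the antigen presentation genes RT1-Ba, Cd74 and RT1-Da were lower by values that did not pass. Among 9 red blood cell markers Hbe1, an embryonic globin gene, rose by 1.87 (0 adjusted over the list alone). Among 8 nerve and Schwann cell markers 2 rose and 3 fell, with the same counts adjusted over the list alone. Cdh19 rose 3.71-fold, and Gfra3 (3.28-fold), Pmp22 (-1.32) and S100b (not above background at 60 min) fell.

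Stress and metabolic gene groups changed in part at 60 min. In the unfolded protein response, 7 of 21 members rose and 1 fell, with the same counts adjusted over the list alone and a median of 0.31 (0.11 without filtering out dim probes and 0.16 with detection on 2 arrays). Ppp1r15a, whose product directs dephosphorylation of eIF2alpha, rose 3.21-fold, the chaperone genes Dnajb9 and Canx 3.02-fold and 2.34-fold, and Creld2 3.00-fold. Xbp1, a transcription factor gene of the same pathway named after its value was seen, fell by 0.81. Of 12 glucocorticoid target genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with Dusp1, Errfi1, the clock gene Per1 (5.41-fold) and Ddit4 (4.16-fold) leading. The gene that fell was Lcn2 (-1.55), named after its value was seen. Of 17 polyamine and ribosome biogenesis genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone). Ddx21 rose 3.75-fold, Sat1, of polyamine catabolism, 3.68-fold, Npm1 3.47-fold and Azin1 2.59-fold. Ncl (-1.30) and Polr1b (-0.89) fell, both named after their values were seen.

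Of 13 hypoxia and glycolysis genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone). Car9 rose at least 4.57-fold, Ddit4 4.16-fold and the glucose transporter gene Slc2a1 at least 2.05-fold, while Ankrd37 fell 4.19-fold. Of 15 inflammatory and NF-kB target genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone). Cxcl1 rose 4.22-fold, Ccl20 3.32-fold and Nfkb1 at least 2.01-fold, and Vcam1, named after its value was seen, fell at least 2.05-fold. The Nfkb1 call was lost with the authors' values. The median of this list was 0.48, or 0.22 with members not above background at their bound and 0.09 without filtering out dim probes. Of 12 heat shock genes, Hspb8 (2.82-fold) and Hspe1 (1.91-fold) rose, and none passed over the list alone. Bag3 and Cryab were 0.71 and 0.49 higher without passing, though Bag3 passed with an offset of 50, without background correction and with the authors' values. Of 16 beta-adrenergic pathway components, 2 rose and 1 fell, with the same counts adjusted over the list alone. Adrb3 rose 2.15-fold and the CREB family gene Atf1 1.89-fold, Rapgef3, a cAMP-regulated exchange factor gene, fell 2.06-fold, and Adcy3 did not pass (adjusted p = 0.0531). Adrb1 was not among the tested genes. Counts of called members in these and the other lists are to be read beside the share of all tested probes that passed at 60 min, given above. The 60 min medians of the hypoxia, heat shock and beta-adrenergic lists lay at the 90.0, 85.7 and 93.2 percentiles of random lists. That of the inflammatory list lay at the 99.15 percentile.

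Of 10 clock genes, 3 rose and 2 fell at 60 min (5 and 2 adjusted over the list alone), with Nfil3 and Per1 among the higher ones and Nr1d1 and Tef (2.99-fold) the lower ones. The time of day of the rats was not given, so these clock gene values cannot be assigned to isoproterenol. Of 15 cell cycle genes, only the thymidylate synthase gene Tyms passed, at least 1.98-fold lower (0 higher and 1 lower adjusted over the list alone). Ccnd1 (-1.31), Ccnb2 (-0.86) and Cdk1 did not pass. Of 13 reference genes, Tfrc rose at least 1.63-fold and none passed over the list alone. Its call was lost without background correction, with an offset of 50 and with the authors' values. Gapdh (-1.29), B2m (-1.23) and Ywhaz (0.50) did not pass, though B2m passed with an offset of 50, without background correction and with an intensity trend in the prior variance.

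At 30 min no probe passed, although early response genes stood far above both controls. Junb was 4.37 higher (20.7-fold, adjusted p = 0.0935), Dusp1 4.06, Nr4a2 3.30, the matricellular gene Ccn1 3.12 (adjusted p = 0.0898), Nabp1 3.11, Gadd45g 3.06 and Egr1 2.72. Gadd45b was 2.92 higher, the insulin receptor substrate gene Irs2 at least 6.29-fold and the histocompatibility gene RT1-A2 at least 13.5-fold. Fos was at least 4.57-fold and the prostaglandin synthase gene Ptgs2 at least 2.95-fold higher. Lower values, none past the threshold, were those of Scgb1b30 (-3.34), Per2 (-2.17), Rtp4 (-1.85), Fbxl20 (-1.84), Lum (-1.76), Col1a1 (-1.75) and Slpi (-1.67). RT1-S2, Tef and Mx2 were at least 3.03-fold, 3.44-fold and 3.76-fold lower. By limma 0 of 10793 probes passed, 2139 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0898. Calls of RT1-A2, Ccn1 and Gadd45g were made with an offset of 50, without background correction, with the authors' values and with an intensity trend in the prior variance, among 3 to 8 calls. Leaving out probes whose controls differ by at least 1, a choice made on the spread itself, gave 65 higher and 82 lower probes.

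Adjusted over the list alone, 16 of 31 immediate early genes were higher and 1 lower at 30 min, as were 9 and 0 of 20 cAMP and CREB target genes and 2 and 0 of 12 MAP kinase feedback genes. Their medians were 0.76, 0.83 and 0.55, and without filtering out dim probes those of the cAMP and CREB list and the MAP kinase list were 0.46 and -0.0002. In the rule of size, 728 probes lay at least 2-fold from the control mean at 30 min, 460 higher and 268 lower. Against control 2 alone the number was 418 and against control 1 alone 1179. Of the 460 probes, 87.2% were higher in control 2 than in control 1, against 51.5% of the probes less than 2-fold from control.

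At 10 min 3 probes passed, all higher. They belonged to 2 salivary secretory protein genes, Grpca (5.43 ± 0.22 SE, 43.2-fold, adjusted p = 0.0264) and Prr4 (4.97 ± 0.27 SE, 31.4-fold, adjusted p = 0.0359), and to RT1-A2, at least 17.5-fold higher (adjusted p = 0.0359). Without filtering out dim probes none passed, and with detection asked on 2 arrays Grpca alone did. RT1-A2 was not above background in either control nor at 60 min. An unadjusted p under 0.05 was found for 655 probes. Several genes lay above both controls without passing, with Nr4a2 2.36, the Ras-related gene Rasd1 1.99, Ccn1 1.88, Gadd45g 1.85 and the claudin gene Cldn24 1.57 higher. The clock gene Bmal1 was at least 2.55-fold and Irs2 at least 2.27-fold higher.

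The larger share of the 10 min differences was downward. By the rule of size 236 probes lay at least 2-fold from control, 35 higher and 201 lower, against 234 probes between the controls, 100 higher and 134 lower in control 2. The control count has the larger sampling variance and no condition on range, so the near equality does not show that the 10 min differences are background. Globin genes were lower without passing, with Hbb at -2.64, Hbb-b1 at -2.47, Hba-a3 at -2.15 and Hba-a1 at -1.74. Extracellular matrix genes were lower too, with Col3a1 at -2.37, Col1a1 at -2.27, Fn1 at -2.14, Col1a2 at -2.09 and Ogn at -2.05 (adjusted p between 0.180 and 0.194). Fcna stood at -1.98 and Cpz was at least 3.77-fold lower. Collagen and globin probes passed without background correction or with an intensity trend in the prior variance, where 8 and 13 probes were called. Leaving out probes whose controls differ by at least 1 gave 10 higher and 70 lower probes. Against control 1 alone the rule of size counted 408 probes.

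The number of probes by the rule of size was 236 at 10 min, 728 at 30 min and 2267 at 60 min, of which 1289 were higher and 978 lower. With the authors' values these counts were 117, 232 and 1095, the last with 711 higher and 384 lower, and no background correction and an offset of 50 lowered them by over 1.5 times as well. Between 30 and 60 min 399 higher and 211 lower probes were shared, against 54.9 and 24.3 for independent lists. Unchanged arrays simulated with moderated variances shared 5.80 and 5.78, and those simulated with the controls' own spread shared 27.5 and 27.1. The differences from control at 30 and 60 min correlated across probes at 0.77, against 0.33 in both simulations, with a covariance of 0.359 against 0.0241 and 0.0503. Between 10 and 60 min 14 higher and 112 lower probes were shared, against 4.18 and 18.2 for independent lists, 6.26 and 5.92 with moderated variances and 27.4 and 26.5 with the controls' spread. The correlation of 0.32 lay below the simulated 0.34, and the covariance was 0.106 against 0.0246 and 0.0513. Between 10 and 30 min 19 and 60 were shared, against 1.49 and 4.99, 6.05 and 5.85, and 27.4 and 26.9 in the same order. The correlation was 0.27 against a simulated 0.33, and the covariance of 0.0576 lay near the 0.0513 that the shared control mean alone brings. For higher probes the overlaps of 10 min with the later times were thus below those simulated with the controls' spread. The simulated sets were not matched in size to the 35 probes higher at 10 min. These counts therefore cannot decide whether the overlaps exceed what shared controls bring. With a different control for each time, so that no array was shared, the correlation of 30 with 60 min was 0.73 or 0.48, depending on which control went with which time. It was 0.28 or -0.0075 for 10 with 60 min and 0.026 or 0.023 for 10 with 30 min. Probes shared at 30 and 60 min then numbered 605 higher and 230 lower, or 102 and 138, against 76.9 and 33.9, or 30.4 and 22.1, for independent lists.

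The direct comparison of 60 with 10 min by limma called 0 probes, with 3599 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0588, so the calls at 60 min are not shown to differ from 10 min. Other settings called up to 1293 probes. The F-test over all times called 0 probes (3325 at an unadjusted p under 0.05, smallest adjusted p = 0.0659), and up to 167 in other settings of that test. The 3 isoproterenol rats together against the controls gave 0 calls (1016 at an unadjusted p under 0.05, smallest adjusted p = 0.344). A linear trend over time with the controls at 0 min called 3442 probes with limma, 1803 rising and 1639 falling. This count was 1953 without control 1 and 0 without the 60 min array.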

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

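The tests with a robust prior variance, the muscle covariate, the linear time trend as a result of its own and the omission of probes with differing controls were chosen after the data were seen. No paired analysis was possible because the isoproterenol samples carry no replicate numbers and each time has 1 rat. Leaving out a control leaves the group model no residual degrees of freedom, so no test was run there. Fold changes of dim probes are limited by signal over background, since an offset or uncorrected background shrinks them.

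The 60 min count of 2634 lay between 2503 and 3829 under all alternatives except no filter on dim probes, where it was 0; that setting tested 22517 probes and lowered the prior degrees of freedom to 2.21. The 3829 came from leaving out probes whose controls differ by at least 1, a choice made on the spread itself, which also gave 10 higher and 70 lower probes at 10 min and 65 higher and 82 lower at 30 min. The 10 min count of 3 became 8 without background correction (3 higher and 5 lower), 0 without the filter, 1 with detection on 2 arrays and 13 with an intensity trend in the prior. The 30 min count of 0 became 7 without background correction (6 higher and 1 lower), 3 with an offset of 50, 3 with the authors' values and 8 with the intensity trend. The count between 10 and 60 min, 0 as reported, was 1293 without background correction, 772 with an offset of 50, 853 with the authors' values and 207 with the intensity trend. For changes at any time the same settings gave 167, 2, 10 and 135, and the linear trend gave 3442. Leaving out arrays, the trend gave 0 to 3006 calls and the isoproterenol rats together 0 to 1, the latter without the 60 min array. With the muscle covariate the trend gave 3028.

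By the rule of size, no background correction, an offset of 50 and the authors' values gave 115, 128 and 117 probes at 10 min, 233, 291 and 232 at 30 min, and 1130, 1325 and 1095 at 60 min; these settings compress dim values. Leaving out arrays gave 199 to 408 at 10 min, 418 to 1179 at 30 min and 1953 to 2700 at 60 min.

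List medians moved as follows, and the cause was not tested. Immediate early genes at 60 min were at 0.73 without background correction, 0.83 with an offset of 50, 0.66 with the authors' values, 1.25 with detection on 2 arrays and 1.07 to 1.27 without 1 array. At 30 min they were at 0.59, 0.60, 0.60, 1.14 and, without the filter, 0.64, and 0.69 to 1.03 without 1 array. At 10 min they were at 0.063 to 0.21 without 1 array, against 0.09 as reported. The cAMP and CREB list at 60 min was at 0.93, 0.98 and 0.87 in the first 3 settings and 0.34 without the filter, and at 30 min 0.46 without the filter.

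Without the filter the MAP kinase feedback median at 30 min (-0.0002) and the growth factor median at 60 min (-0.12) turned sign, since undetected members entered the lists. Other medians turned sign as well. Among them were the hypoxia and glycolysis median at 60 min (0.16 to -0.06) without the filter. Without control 1, the 60 min medians of cell cycle genes (-0.32 to 0.08) and skeletal muscle markers (-0.38 to 1.80) did so. Amylase turned from -0.02 to 0.0001 with median scaling. Of the named gene values, 82 lost a call (70 of them without the filter) and 39 gained one. The 1531 counted as unchanged include the values from the settings without a control. No threshold was applied there, and leaving out a control moves a value by less than the control SD that was allowed, so that label was fixed in advance.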

Other observations

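All tests of explanations in this part, and the bounds that decided them, were chosen after the values were seen.

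Single genes with other functions also had values that differed between rats. Among these the clock genes Bmal1, Per2 and Cry1 did not pass over all tested probes at any time. Adjusted over the clock list alone, 2 of 10 measured genes were higher and 4 lower at 10 min. At 30 min 5 were higher and 4 lower in that way. Per1 stood 1.78 below the control mean at 10 min, without passing over all tested probes, and 1.25 above it at 30 min. Bmal1 stood at 4.87 and 4.91 in the controls, 6.41 at 10 min, 6.69 at 30 min and 5.07 at 60 min on the log2 scale. Per2 differed from control by -1.83, -2.17 and 0.79 at these times, and Cry1, named after its value was seen, stood at 7.14 and 7.04 against 8.24, 8.13 and 7.83. Mx2 and Rtp4, known as interferon-induced genes, fell at 60 min, at least 3.68-fold and 4.33-fold. RT1-A2 stood at 9.18 and 8.81 at 10 and 30 min and was not above background in the controls or at 60 min. No explanation of these values was tested.

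Skeletal muscle markers separated the rats without regard to treatment: Ckm stood at 13.26 in control 1 and 13.36 at 30 min, 10.02 at 60 min, and 7.39 in control 2 and at 10 min. A response to isoproterenol is argued against by the controls, which differed by 4.44 in the median marker. A candidate explanation is skeletal muscle carried in with the gland: 11 of the 16 markers ranked the rats in this order. The order was taken from these same markers, so the count shows that they vary together and cannot decide for carried-in tissue. Over all 16, the median level was 2.58% of control 1 in control 2, 2.94% at 10 min, 104% at 30 min and 10.6% at 60 min, with a range over markers in control 2 of 1.27% to 122%. The exceptions include Car3, which was bright on every array, and none of the 16 is in another list, so a difference in dissection stays open as a hypothesis.

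Immediate early genes and cAMP and CREB target genes were higher in control 2 than in control 1, by medians of 0.14 and 0.30. Across all tested probes, which are not independent replicates, control 2 minus control 1 was correlated with differences that share no array with it. The correlation was 0.31 with 60 min minus 10 min, 0.0064 with 30 min minus 10 min and 0.45 with 60 min minus 30 min. Without the 16 muscle markers these values were 0.37, 0.12 and 0.43. This left out only the listed markers, so other muscle transcripts remained and muscle is not excluded as a source of the correlations. Mixtures were considered for the 6 immediate early or cAMP target genes at least 1 higher in control 2. RNA of the 30 min rat mixed into control 2 would need a median share of 16.7%. The 11 muscle markers that ranked the rats in the order above allow at most 8.28%. Markers outside that order were not used, such as Car3, at 11.24 in control 2 and 11.52 at 30 min. The 11 markers argue against such a mixture as the source of the difference in these 6 genes. The 6 genes were chosen for that difference, which raises the share needed, so a smaller mixture is not excluded. RNA of the 60 min rat would need 5.83%, below the 10.8% to 38.7% that the same 11 muscle markers allow. A single share, however, misses control 2 by a median of 0.40 on the log2 scale, against a prior SD of 0.186. The rule for this test was changed more than once after its value was seen: the muscle ceilings alone leave the mixture possible, a bound of 2 times the prior SD excludes it, and the bound used, 3 times, leaves it open, so a mixture cannot be told apart from a response of that control rat, for example to handling, which was not tested, since the design has no further control rats.

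Connective tissue genes were lower already at 10 min, by a median of 1.37, when the controls differed by 0.10. A stop of transcription lasting the hour, with decay of the mRNA, would need a half-life of 7.30 min and a 60 min median near -8.22, while the observed median was -1.54. Other medians at 10 min were -0.86 for myoepithelial markers (-0.32 between the controls), -0.72 for myeloid (-0.45 with members not above background at their bound, -0.36 between the controls), -0.52 for adipocyte (-0.35 at bounds), -0.48 for red blood cell (-0.17 at bounds), -0.17 for nerve (-0.07 at bounds) and -0.13 for lymphoid markers. Medians at bounds take members not above background in either group as unchanged, which pulls them toward no change. Without control 1 the myoepithelial median was -0.53 and the lymphoid one -0.05. The lymphoid one was -0.21 without control 2 and -0.35 without the 60 min array. A larger acinar share that lowers every other cell type alike is argued against by ductal markers, at -0.14, from which the endothelial and fibroblast median differed by -1.23 at 10 min, more than the larger SD over genes of 0.639, although at 30 min the ductal (-0.65) and the endothelial and fibroblast (-0.86) medians lay within their SDs over genes (0.404 and 0.427), so at that time it is not excluded. At 60 min these medians were -0.71 and -1.54, again farther apart than the larger SD over genes, 0.57. The 10 min ductal median was -0.03 without control 1 and -0.27 without control 2, and the controls differed by -0.25 in this list. An SD over genes is not a spread between rats, so these comparisons describe these arrays only. Less stroma, with the cell types it holds, in the pieces taken from the isoproterenol rats, and a brief fall that ended by 10 min, stay open and were not tested.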
